A study of Rattus norvegicus with 52 samples.

How the data were processed

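Gene expression was measured in rat dorsal root ganglia on two-colour oligonucleotide arrays, with 52 hybridisation channels in 16 groups. The labels name a series of SN samples and a series of DR samples, each at 7 times (6, 12, 24, 48 and 72 h, 7 and 14 d), and a control group for each series, CON(SN) and CON(DR). The labels give only these abbreviations; from what is known of the study, SN stands for a lesion of the sciatic nerve, the peripheral branch of these neurons, and DR for a lesion of the dorsal root, their central branch. Per the labels' design text, each RNA sample was 1 pool of 3 animals, was hybridised at least 3 times and met each dye at least once in an interwoven loop. The channels of a group are therefore repeated hybridisations of 1 pool: their p-values measure only the spread between hybridisations of that pool, and animals and lesion cannot be told from the pool. Groups had 3 channels, except DR6h and DR48h with 4 and DR12h with 5. The number of arrays limits the precision.

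The channel values are intensity values on a linear scale that the authors deposited already normalised, by a method not given in the sources used here. Their quartiles were nearly alike across the 52 channels, with medians from 120 to 125, lower quartiles from 67 to 69 and upper quartiles from 376.5 to 397; single values ran from 9 to 90077. The authors also deposited a log2 coefficient for each lesion and time against their time zero, and its standard error, made with limma per the submitters' processing notes, which give no version. Values from that source are named below as the authors' deposited table. The planned model assumed log2 values, or their log2 where linear; as the values were linear, log2 was taken with no pseudocount and no further normalisation. Background correction was not given in the sources used here. No filter on dim probes was applied.

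The arrays carried 8455 probes, all tested. The annotation listed 7075 of them, 6907 with 1 gene symbol and 168 with several; the latter were not named, and the 1380 that it does not list are unnamed here. Symbols were updated through gene identifiers for 6885 probes and through accessions for 3, and 19 kept the symbol of the annotation. In all, 6028 genes were named, 751 of them by several probes; the probe with the highest mean value stood for its gene.

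All tests used limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all probes of a contrast. A linear model with group and dye as terms was fitted to all 52 channels, which share an estimate of the spread. A moderated F test over the 7 times of a lesion against its own control gave the courses, and a probe was called at an adjusted p below 0.05 with at least 1.5-fold change at any time. Each time was also tested singly with the same limits. The difference between the lesions' courses was tested as an interaction over the 7 differences of changes. Because the pool and not the channel is the independent unit, further fits used the mean of each pool after removal of the dye term: 7 SN pools against 7 DR pools paired by time, each lesion's 7 pools against the 2 control pools, and 8 later pools (48 h to 14 d) against 6 earlier pools (6 to 24 h), at an adjusted p below 0.05. The SN and DR arrays formed separate loops, so a direct comparison of SN with DR levels holds any difference between the 2 sets of arrays. Gene lists were tested with camera, at an inter-gene correlation of 0.01, on the mean of 7 times against the own control and on the paired pool difference. The 26 lists, fixed before the data were examined, held 518 genes, of which 374 were measured.

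Named genes followed a rule fixed before the data were examined: for each course the 12 called genes with the largest rise and the 8 with the largest fall at their peak time; for the paired pools the 12 highest and 8 lowest genes past the threshold with all 7 pairs in 1 direction; for the control pools and for later against earlier pools the 5 highest and 5 lowest called; 2 to 4 genes of each list with the largest changes; and 11 genes known from nerve injury, whatever their values (Atf3, Jun, Sox11, Gap43, Gal, Npy, Vip, Sprr1a, Nfil3, Stat3 and Smad1).

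The files give no array for a channel. After the data were seen, channels were joined into 26 arrays (12 SN and 14 DR) by matching Cy3 with Cy5 channels within each lesion. The joins kept the log2 differences of the channels near the differences of the authors' deposited coefficients. In 24 of the 26 joins no other Cy5 channel lay nearer to the Cy3 channel. The channel residuals did not enter, and 17 of the 26 joins were also mutual best matches by these residuals alone. The relative standard errors of this layout matched the deposited ones (largest difference 0.0). They depend on which groups shared an array, not on which channels of a group did. On these inferred arrays the Cy5 minus Cy3 difference was fitted with a dye term, and the result is called the within-array value. It removes what the channels of an array share. The lesions were compared there by the mean SN change minus the mean DR change, with the error of both controls. A paired test on values relative to the own control was not used for calls, since the 7 values of a lesion share its control: with no change simulated 20 times it called 2798 to 3087 of 8455 probes within arrays, and the difference of means 0. Since the joins rest on the authors' deposited table, likeness to it is in part by construction. The likeness was measured only for a fit on these arrays without a dye term, not for the within-array values used below. Across probes that fit correlated with the table at Pearson r from 0.943 to 0.992 over the 7 SN times. Over the 7 DR times r was from 0.555 to 0.698, and the DR difference was not resolved.

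The programs were tested on simulated data of 8455 probes in which 200 were changed. For the SN course with independent channels, 13.4% of probes changed 1.5-fold, 62.7% changed 2-fold and 98.5% changed 4-fold were recovered with 0 false calls by limma, and 1.49%, 11.9% and 72.7% with 1 false call by the within-array fit; where channels of an array shared their deviation (correlation 0.774, estimated from these data), the channel fit recovered 7.46%, 64.2% and 93.9% with 2 false calls and the within-array fit 17.9%, 85.1% and 98.5% with 10. The paired pool fit recovered 73.1%, 95.5% and 100% with 14 false calls. Its pools were simulated as independent, with no offset between the SN and DR arrays, so these false calls do not cover such an offset. Among 26 lists over 6028 genes, camera called the 1 shifted list and no other. Genes were independent in that simulation, so it does not cover correlation within a list.

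Alternatives fixed before the data were examined were quantile or median scaling, no dye term, no dim probes (the lowest 25% by mean value), an adjusted p of 0.01, no or a 2-fold minimum, a replicate block, the authors' deposited coefficients, and each channel or time left out in turn; those added after seeing the data were the array as a random block, the within-array fits and the fits without 2 arrays that stood apart. Array matching, annotation and drawing used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.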

Results

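Expression in rat dorsal root ganglia was followed after SN and DR lesions at 6, 12, 24, 48 and 72 h and at 7 and 14 d, in 14 lesion pools and 2 control pools, with 3 to 5 hybridisation channels for each. The labels describe regenerating dorsal root ganglion neurons, which addresses how the ganglion's expression changes over time after each lesion. Channel medians lay between 120 and 125. Values below are log2 differences from the lesion's own control pool ± SE, and intensities are means ± SD over the channels of a pool.

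After the SN lesion 3 of 15 measured neuropeptides rose, and their list was not called (adjusted p = 0.184). Npy, which encodes neuropeptide Y, rose from 352 ± 325 (n = 3) to 9030 ± 1240 (n = 3) at 14 d. That was a log2 difference of 5.05 ± 0.46 and a 33.2-fold change. The log2 value was 4.68 without CON(SN) replicate 2, 5.78 without replicate 3 and 3.65 in the authors' deposited table. Galanin (Gal) rose by 4.18 ± 0.67 at 72 h (3.22 without CON(SN) replicate 2 and 4.83 without replicate 3) and vasoactive intestinal peptide (Vip) by 3.44 ± 0.26 at 14 d. The stress-inducible transcription factor Atf3 rose by 4.19 ± 0.22 at 24 h, an 18.2-fold change, with an adjusted p over the course of 2.32e-21. Within arrays the same genes rose by 3.48 (Npy), 3.07 (Gal), 3.10 (Vip) and 4.09 (Atf3).

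Csrp3, a muscle LIM protein, rose by 4.34 ± 0.20 at 72 h, from 97.3 ± 31.0 to 1980 ± 133 (n = 3 channels each). Ankrd1, a cardiac ankyrin repeat protein, rose by 2.83 ± 0.21 and Tgm1, a transglutaminase of the skin barrier, by 2.55 ± 0.22 at 48 h. Also at 48 h, the arginine-degrading enzyme Arg1 rose by 3.10 ± 0.21, the peptide urocortin (Ucn) by 2.88 ± 0.19 and the small GTPase Rrad by 2.68 ± 0.20. The secreted lectin Reg3b rose by 4.08 ± 0.29 at 72 h, and RT1-Da, a class II antigen presentation gene, by 2.61 ± 0.34 at 14 d (2.00 without CON(SN) replicate 2). Within arrays all 12 of these largest rises were also called, at 1.99 to 4.29.

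Among the largest SN falls, the defensins Np4, Defa5 and RatNP-3b fell by 2.37 ± 0.24 (14 d), 2.06 ± 0.23 (14 d) and 1.98 ± 0.27 (7 d). The beta globin gene Hbb fell by 2.18 ± 0.19 at 14 d, from 12300 ± 535 to 2710 ± 239 (n = 3 channels each). The mast cell and basophil proteases Mcpt10 and Mcpt8 fell by 1.63 ± 0.20 (14 d) and 1.53 ± 0.21 (72 h), and the cytoskeletal Septin7 by 1.32 ± 0.25 at 72 h. Each of these 7 was also called over the SN course within arrays. Gap43, a growth cone protein, was the exception among the 8 largest falls: the channel value of -1.92 ± 0.95 at 12 h became 0.03 within arrays and is 0.25 in the authors' deposited table. It is not read as a fall.

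Over the SN course, limma called 417 of 8455 probes, 253 higher and 164 lower at their largest change. Within arrays 318 were called, 216 higher and 102 lower, and 207 probes were called the same way in both.

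The 11 genes fixed in advance followed separate times. Atf3 was at 0.07 ± 0.22 at 6 h (1 in the authors' deposited table), 2.78 ± 0.22 at 12 h and 3.79 ± 0.22 at 14 d after the SN lesion. The small proline-rich Sprr1a rose by 1.12 ± 0.24 at 48 h (within arrays 0.84) and the transcription factor Nfil3 by 0.78 ± 0.16 at 24 h (within arrays 0.64, adjusted p 0.0519 at that time). Smad1, a signal transducer of bone morphogenetic proteins, passed the SN course test with a largest value of 0.79 ± 0.23 at 72 h (course adjusted p 0.00406, within arrays 0.0495). Jun, an early stress transcription factor, rose by 1.12 ± 0.27 at 7 d (within arrays 1.76). It passed the SN course test (adjusted p 0.0384), and did not without CON(SN) replicate 1 or 3 or without SN7d replicate 1, 2 or 3 (0.92 to 1.17 at 7 d). Gap43 was at 1.79 ± 0.94 at 14 d in the channel fit. Within arrays it rose by 0.90 ± 0.15 at 48 h and 1.71 ± 0.15 at 14 d (adjusted p 9.12e-06). A dimmer probe of Gap43 passed the SN course in both fits, at 1.42 and, within arrays, 1.33 at 14 d. Sox11 passed the SN course in the channel fit (adjusted p 0.0329) and not within arrays (0.679). Its largest value there was a fall, -0.68 ± 0.30 at 6 h, not called at that time (adjusted p 0.504). Its course call was also lost without some single channels. Stat3 did not pass (0.407).

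**Figure D1:**
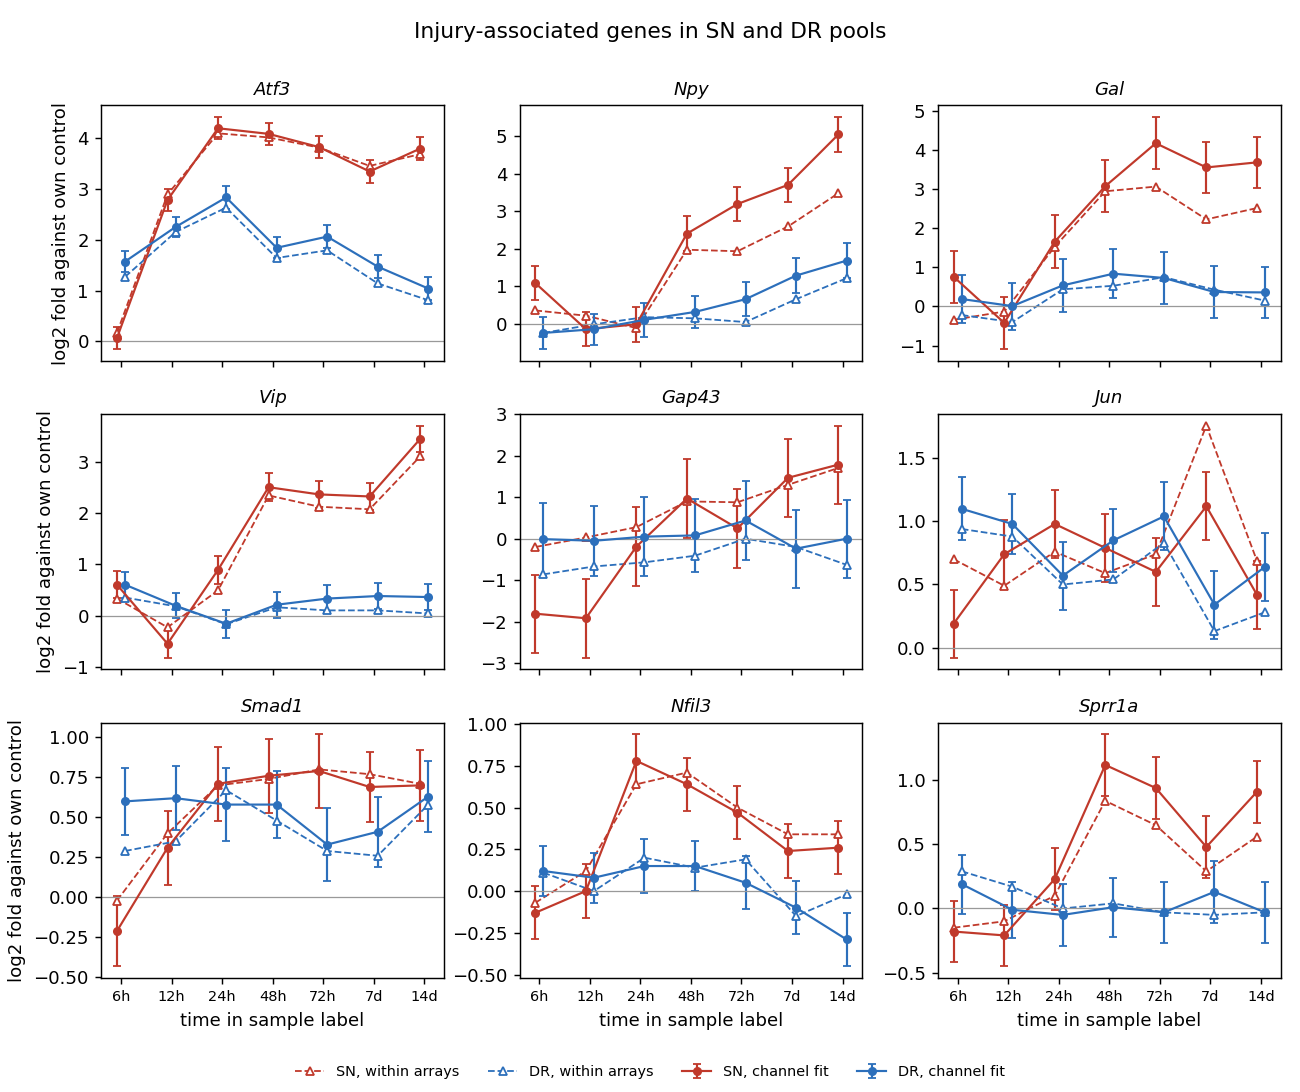
Log2 change from the own control (vertical axes) against time in the sample label (horizontal axes) for 9 injury-associated genes in SN (red) and DR (blue) pools; solid lines with SE bars are the channel fit and dashed lines the within-array values. Npy reached 5.05 in SN and 1.68 in DR at 14 d, while Atf3 rose in both.

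Of the gene lists fixed in advance, camera called 9 of 26 for the mean of the 7 SN times. Among 24 measured growth-associated effectors 6 rose, 0 fell and 18 were not called at an adjusted p below 0.05 in limma, 9 rose when adjusted over the list alone, and the list test gave an adjusted p = 2.2e-15. Its members Reg3b, Arg1, the calcium channel subunit Cacna2d1 and the stathmin Stmn4 rose by 2.89 ± 0.22, 1.44 ± 0.16, 1.00 ± 0.13 and 0.97 ± 0.15. Of 15 antigen presentation genes 3 rose, RT1-Da by 1.13 ± 0.26, the invariant chain Cd74 by 0.92 ± 0.19 and RT1-DMb by 0.66 ± 0.16 (6 adjusted over the list alone; list adjusted p = 1.85e-05). Of 10 macrophage markers 3 rose, Aif1 by 0.81 ± 0.16, the protease Ctss by 0.66 ± 0.16 and the receptor Csf1r by 0.51 ± 0.13 (3 adjusted over the list alone; list adjusted p = 6.43e-05). Of 17 trophic factors, cytokines and chemokines 2 rose, the chemokine Ccl2 by 1.07 ± 0.16 and the macrophage growth factor Csf1 by 0.79 ± 0.11 (3 adjusted over the list alone; list adjusted p = 0.013). These 4 lists kept their calls with an estimated correlation, at adjusted p = 2.65e-08, 0.000219, 0.000361 and 0.0204. Within arrays 2 of them lost their calls that way, the macrophage markers (adjusted p = 0.0514 with an estimated correlation) and the trophic factors (adjusted p = 0.0928 with an estimated correlation). Within arrays RT1-Da (0.71), RT1-DMb (0.74), Ctss (0.64) and Csf1r (0.48) were not called for this mean.

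The other 5 SN lists lost their calls with an estimated correlation. Of 12 complement and acute phase genes 2 rose, the protease inhibitors A2m by 0.72 ± 0.13 and Timp1 by 0.55 ± 0.14 (3 adjusted over the list alone). That list test gave an adjusted p = 0.00463 (adjusted p = 0.0535 with an estimated correlation). Of 20 injury-induced transcription factors 1 rose, Atf3 by 3.15 ± 0.17 (3 adjusted over the list alone). The median of that list was -0.01 against a mean of 0.23 and an upward test (adjusted p = 0.0185, and adjusted p = 0.227 with an estimated correlation). Of 12 interferon response genes 2 rose, Mx2 by 1.28 ± 0.18 and Ifitm3 by 0.63 ± 0.12 (2 adjusted over the list alone). The interferon list had an adjusted p = 0.0266 (adjusted p = 0.0563 with an estimated correlation) and was not called within arrays (0.087). Of 10 red blood cell, adipose and muscle transcripts 1 fell, Hbb by 1.07 ± 0.15 (2 adjusted over the list alone). Its genes had a median of 0.01, a mean of -0.18 and a downward test (adjusted p = 0.0423, and adjusted p = 0.0563 with an estimated correlation). Of 9 myelinating Schwann cell markers 0 were called by limma (1 fell when adjusted over the list alone and 1 had an unadjusted p below 0.05). The downward list test gave adjusted p = 0.0476, and adjusted p = 0.057 with an estimated correlation.

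After the DR lesion Reg3b rose by 3.46 ± 0.29 at 7 d, an 11-fold change, and Atf3 by 2.83 ± 0.22 at 24 h. Snap25, a core protein of synaptic vesicle fusion, rose by 2.27 ± 0.20 at 24 h, from 1670 ± 171 to 8240 ± 1390 (n = 3 channels each). The neuropeptide precursor Vgf rose by 2.09 ± 0.21 and the lipid carrier Apod by 1.89 ± 0.20 at 7 d, and the chemokine Ccl2 by 1.98 ± 0.19 at 12 h.

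At 7 d the matrix protein Fn1 rose by 1.88 ± 0.22, the protease inhibitor A2m by 1.68 ± 0.17 and the lectin Reg3a by 1.57 ± 0.26. The synaptic vesicle protein Sv2b rose by 1.62 ± 0.34 at 14 d, the neuronal calcium sensor Vsnl1 by 1.59 ± 0.22 at 24 h and Npy by 1.68 ± 0.46 at 14 d. In the authors' deposited table Sv2b, Vsnl1 and Npy were at 1.67, 0.79 and 1.28. Within arrays all 12 of these largest rises were also called over the DR course, at 1.21 to 2.98. The 8 largest falls were not alike in both fits. Taf9b, Shb, Ssx2ip, Ins2, Pex3, Syn3 and Vps4a at 14 d and Camk2g at 48 h were at -2.85 to -2.01 in the channel fit. Within arrays they were at -0.46 to 0.35, and 2 of the 8 were called. Ssx2ip, Ins2, Pex3, Syn3, Vps4a and Camk2g also lost their course calls in the channel fit without single channels of CON(DR), DR14d or DR48h. Jun was at 1.10 ± 0.25 at 6 h (course adjusted p 0.0229, within arrays 0.133), against 0.10 in the authors' deposited table, and did not pass without CON(DR) replicate 1 or 2 (1.03 and 1.11), and Gap43 fell by 0.86 ± 0.13 at 6 h within arrays (adjusted p 0.00333) while the channel fit gave -0.01 ± 0.88.

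Over the DR course limma called 660 probes, 427 higher and 233 lower; within arrays 476 were called, 237 higher and 239 lower, of which 239 were called the same way in both. A pair of arrays (22 and 24) stood apart. Their 4 channels, DR48h 4, DR72h 3, DR14d 2 and DR14d 3, lay at 37.8 to 41.7 on the first principal component (22.4% of the variance), against at most 22.1 for any other channel on that side. On the other side DR7d replicate 1 and SN6h replicate 3 lay at -35.1 and -34.8, with the next at -20.4; without DR7d replicate 1 the DR7d count went from 189 to 340, and without SN6h replicate 3 the SN6h count from 20 to 9. Without arrays 22 and 24 the DR course gave 402 probes; without DR14d replicate 2 or 3 it gave 358 or 382, and without DR14d replicate 1 it gave 1201.

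The DR lists moved in 6 cases. Of 17 synaptic vesicle and release genes 6 rose and 0 fell in limma, Snap25 by 1.85 ± 0.15, Rab3a by 0.98 ± 0.16, Syn1 by 0.53 ± 0.15 and Syt4 by 0.52 ± 0.14 (7 adjusted over the list alone). The synaptic list had an adjusted p = 0.000107 (adjusted p = 0.00917 with an estimated correlation). Of 17 extracellular matrix and fibroblast genes 4 rose, Fn1 by 0.97 ± 0.16, Timp1 by 0.71 ± 0.14, Col1a2 by 0.51 ± 0.16 and Col4a1 by 0.50 ± 0.11 (8 adjusted over the list alone). The matrix list had an adjusted p = 0.000686 (adjusted p = 0.0231 with an estimated correlation). Of 12 complement and acute phase genes 4 rose, A2m by 1.01 ± 0.13, Timp1, Cfb by 0.65 ± 0.14 and C1s by 0.64 ± 0.12 (4 adjusted over the list alone). The complement list had an adjusted p = 0.000739 (adjusted p = 0.0309 with an estimated correlation). Of 24 growth-associated effectors 5 rose, among them Reg3b by 2.12 ± 0.22, Reg3a by 0.83 ± 0.20 and the adhesion molecule L1cam by 0.69 ± 0.17 (8 adjusted over the list alone). The growth-associated list had an adjusted p = 0.000739 (adjusted p = 0.00917 with an estimated correlation). These 4 lists were also called within arrays, where Syn1 (0.35), Col4a1 (0.26) and Reg3a (0.62) were not called. Of the 4, the growth-associated list lost that call (adjusted p = 0.0125 within arrays, and adjusted p = 0.133 with an estimated correlation).

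The other called DR lists lost their calls with an estimated correlation in the channel fit. Of 29 oxidative phosphorylation genes 4 fell and 1 rose. The respiratory chain subunits Ndufv2, Cox7a2, Cox5b and Ndufs3 fell by 0.75 ± 0.18, 0.69 ± 0.19, 0.65 ± 0.13 and 0.48 ± 0.15 (9 fell and 1 rose adjusted over the list alone). Their list had an adjusted p = 0.000107 (adjusted p = 0.0522 with an estimated correlation). Within arrays it had an adjusted p = 0.0197 and kept its call (adjusted p = 0.048 with an estimated correlation). Of 20 injury-induced transcription factors 6 rose, among them Atf3 by 1.87 ± 0.17, the hypoxia factor Hif1a by 1.16 ± 0.18 and Klf7 by 0.66 ± 0.20 (6 rose and 1 fell adjusted over the list alone). That list had an adjusted p = 0.000243 (adjusted p = 0.0731 with an estimated correlation) and was not called within arrays (0.0706). Within arrays Ndufv2 (-0.32), Cox7a2 (-0.35) and Cox5b (-0.35) were not called, and Cox4i1, the subunit that rose by 0.44 ± 0.11, was not called either.

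**Figure D2:**
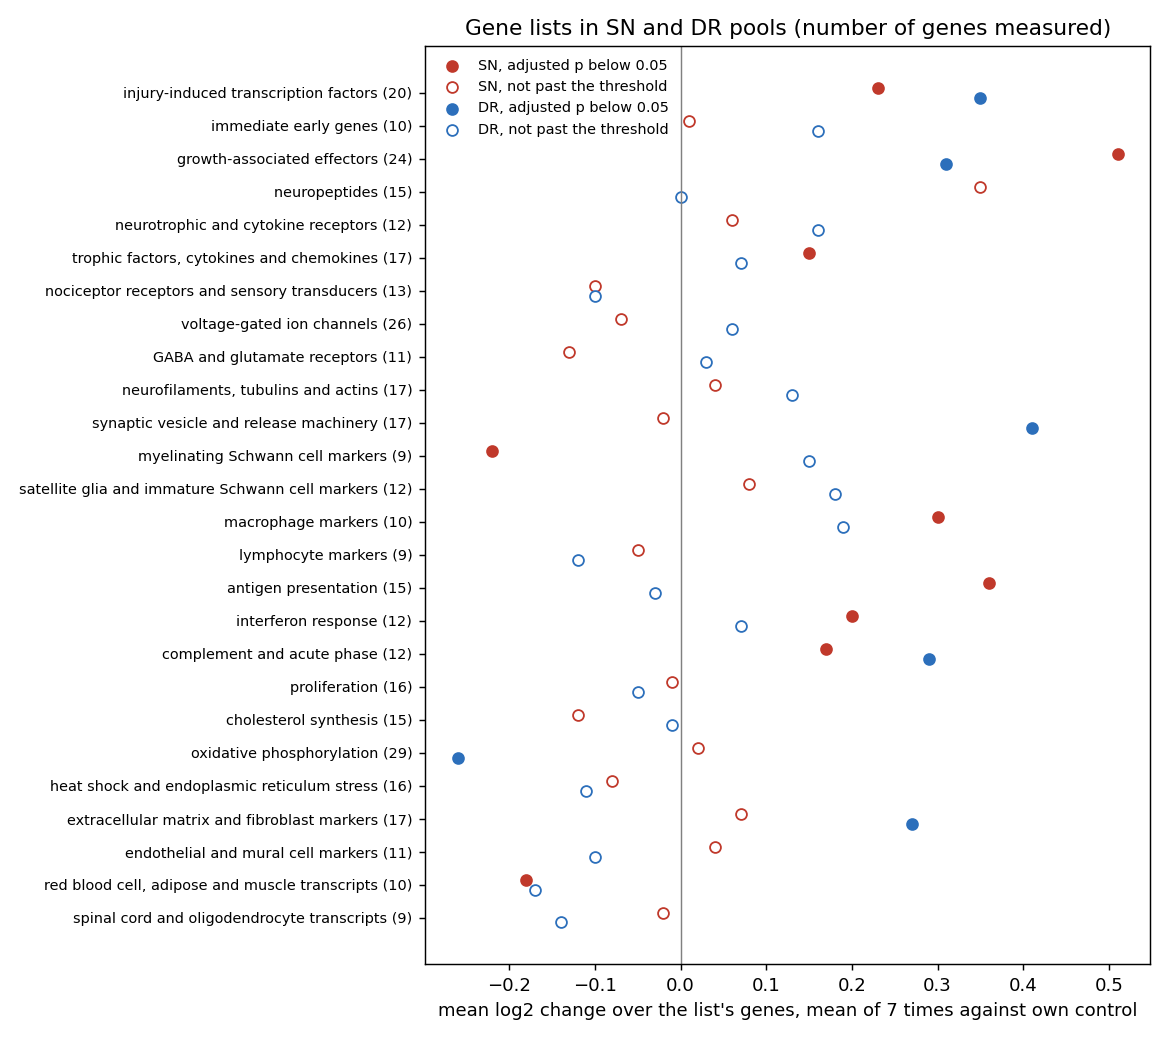
Mean log2 change of each gene list over the 7 times against the own control (horizontal axis) for SN (red) and DR (blue); filled points passed an adjusted p of 0.05 and the number of measured genes stands beside each list. SN growth-associated effectors lay at 0.51 and DR synaptic vesicle genes at 0.41.

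The remaining 14 lists were not called for either lesion, and some of their members named here passed in the channel fit and not within arrays (Gfra1, Csf1r, Htr3a and Pdia4 in SN, and Ntrk3, Cfl1, Ncam1, Cspg4, Gabbr2, Mcm4 and Msmo1 in DR). Npy, Gal and Vip among 15 neuropeptides rose in SN and Nmb, another peptide, fell by 0.84 ± 0.12 in DR (adjusted p = 0.184 and 0.569). The DR mean of Nmb was -0.21 in the authors' deposited table. Other DR means given here were also smaller in that table, as for Cacnb3 (0.21), Timp1 (0.17) and Ctss (0.15), while A2m (1.02) and Ccl2 (1.31) stayed near. Among 12 neurotrophic and cytokine receptors the GDNF receptor Gfra1 rose by 0.73 ± 0.17 and Csf1r by 0.51 ± 0.13 in SN, and in DR the neurotrophin receptor Ngfr rose by 0.78 ± 0.15 while Ntrk3, another, fell by 0.56 ± 0.16 (0.468 and 0.271). Among 26 voltage-gated ion channels Cacna2d1 rose in SN, and in DR 3 rose and 1 fell, the potassium channel Kcna1 by 0.82 ± 0.13, with the largest rise in the calcium channel subunit Cacnb3 by 0.94 ± 0.16 (0.342 and 0.56). The serotonin receptor Htr3a, among 13 nociceptor receptors and sensory transducers, fell by 0.73 ± 0.16 in SN (0.321 and 0.387). Among 17 neurofilaments, tubulins and actins 4 rose and 2 fell in DR, with rises of the microtubule proteins Map1b and Map2 by 1.15 ± 0.16 and 0.68 ± 0.18 and of the actin regulator Cfl1 by 0.89 ± 0.19 (6 and 3 adjusted over the list alone; 0.476 and 0.22). The 2 that fell, named after their values were seen, were the neurofilament Nefm by 0.52 ± 0.16 and the microtubule protein Mapt by 0.46 ± 0.13, which was not called within arrays. The chaperone Pdia4, among 16 heat shock and endoplasmic reticulum stress genes, fell by 0.66 ± 0.12 in SN, and 2 fell in DR, Hspe1 the most by 0.57 ± 0.15 (0.342 and 0.401). The glial filament Gfap, among 12 satellite glia and immature Schwann cell markers, rose by 0.98 ± 0.15 in SN and 0.72 ± 0.15 in DR, where Ncam1 rose by 0.63 ± 0.20 (0.468 and 0.121). The pericyte marker Rgs5, among 11 endothelial and mural cell markers, rose by 0.47 ± 0.11 in DR and Cspg4, also of pericytes, fell by 0.40 ± 0.12 (0.795 and 0.416). In DR Gabbr2, a GABA receptor, rose by 0.46 ± 0.15, the replication gene Mcm4 rose by 0.54 ± 0.14 and Msmo1, of cholesterol synthesis, fell by 0.52 ± 0.15. In DR the other lists called for SN had adjusted p = 0.689 (antigen presentation), 0.131 (macrophage markers), 0.56 (trophic factors), 0.543 (interferon response and myelinating Schwann cell markers) and 0.131 (red blood cell, adipose and muscle transcripts). In SN the other lists called for DR had adjusted p = 0.76 (synaptic and oxidative phosphorylation genes) and 0.323 (matrix). Single members passed in the other lesion too. In DR these were Ccl2 by 1.43 ± 0.16, Mx2 by 0.84 ± 0.18, Ctss by 0.63 ± 0.16, Ifitm3 by 0.50 ± 0.12 and Csf1 by 0.39 ± 0.11. On the mean over the times RT1-Da, Cd74, Aif1 and Csf1r were not called in DR, and within arrays Mx2, Ifitm3 and Csf1 were not either. The F test over the DR course gave an adjusted p of 2.66e-07 for Aif1, 3.78e-05 for Cd74, 0.000102 for Csf1r and 0.0492 for RT1-Da. Within arrays the course values of these genes were 0.000367, 0.0212, 0.0311 and 0.117. Those of Mx2, Ifitm3 and Csf1 within arrays were 0.00535, 0.00502 and 0.0193. Snap25 rose by 0.90 ± 0.15 in SN. Adjusted list p values for SN and DR were 0.91 and 0.189 for 10 immediate early genes, 0.0786 and 0.78 for 11 GABA and glutamate receptors, 0.76 and 0.532 for 9 lymphocyte markers. They were 0.76 and 0.983 for 16 proliferation genes, 0.0786 and 0.946 for 15 cholesterol synthesis genes and 0.792 and 0.617 for 9 spinal cord and oligodendrocyte transcripts. In DR the 9 spinal cord transcripts had a median of -0.04, beside the rise of the synaptic list. The median, mean and test also differed in sign for neurotrophic receptors (-0.08, 0.06, up), proliferation (0.00, -0.01, up), oxidative phosphorylation (-0.01, 0.02, up) and endothelial markers (-0.02, 0.04, up) in SN. In DR they differed for neuropeptides (0.04, 0.00, down), trophic factors (-0.01, 0.07, up), antigen presentation (0.05, -0.03, down), proliferation (0.05, -0.05, up) and cholesterol synthesis (0.08, -0.01, up), and between the paired pools for the interferon list (-0.11, 0.02, down).

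Single times differed in number of called probes. In the SN series 15 (12 h) to 157 (72 h) probes were called at a time, and within arrays 3 (6 h) to 171 (48 h). In the DR series the counts were 88 (24 h) to 1029 (14 d), and within arrays 36 (72 h) to 387 (6 h). The 1029 probes at DR14d, 551 higher and 478 lower, compare with 100 within arrays, of which 52 were called the same way in both, and with 14 without arrays 22 and 24, which leaves 1 channel of that pool. Leaving out DR14d replicate 2 or 3 gave 240 or 321 probes, leaving out replicate 1 gave 1781, and leaving out CON(DR) replicate 3 gave 558. At DR6h 346 were called (387 within arrays), and 194 without CON(DR) replicate 3, 225 without DR6h replicate 1 and 207 without DR6h replicate 2. The SN12h count was 8 without SN12h replicate 3, and the SN72h count 90 without CON(SN) replicate 2 and 97 without SN72h replicate 1. The DR24h count was 57 without CON(DR) replicate 1, 170 without CON(DR) replicate 3 and 51 without DR24h replicate 3. Over all 14 comparisons the totals were 628 for SN and 2343 for DR, and within arrays 562 and 1303.

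**Figure D3:**
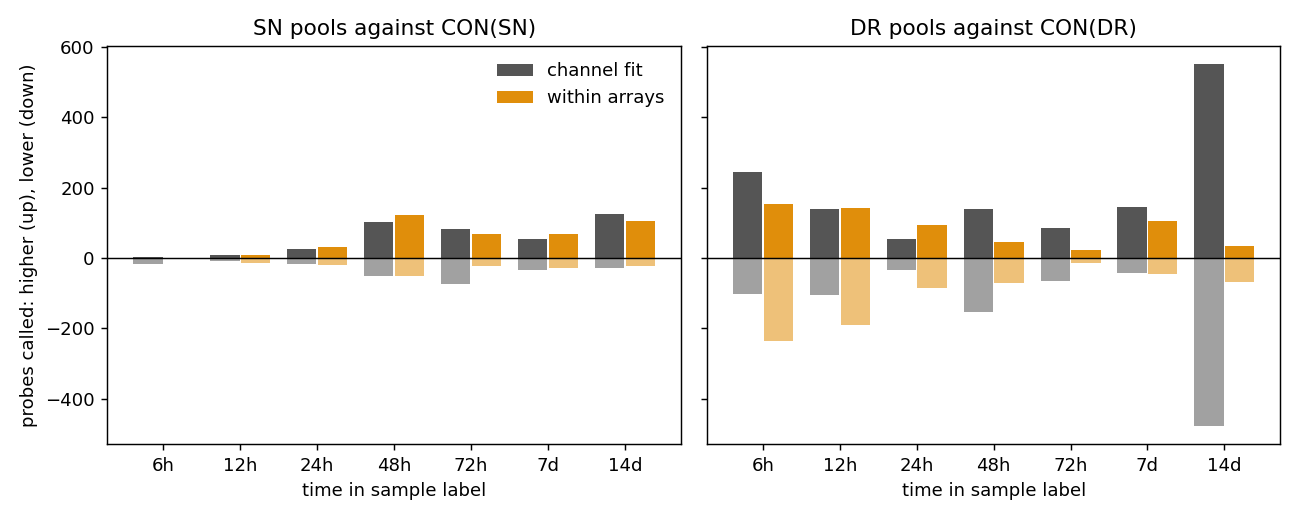
Probes called at each time against the own control (vertical axis, higher above 0 and lower below) for SN and DR, from the channel fit (grey) and within arrays (orange). DR14d had 1029 calls in the channel fit and 100 within arrays.

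The interaction test asked whether a change over time differed between the lesions. Npy, Csrp3, Vip, Gal and Atf3 changed more after the SN lesion at the times given. The difference of changes was 3.37 and 4.08 for Npy (14 d) and Csrp3 (72 h), 3.08 and 3.46 for Vip (14 d) and Gal (72 h), and 2.75 for Atf3 at 14 d. At 6 h Atf3 was the other way, at 0.07 ± 0.22 in SN and 1.57 ± 0.21 in DR (within arrays 0.17 and 1.27). The authors' deposited table gave nearly equal values at 6 h, 1 in SN and 1.11 in DR, so this reversal depends on the processing. Snap25 and Sv2b changed more after the DR lesion, at -1.88 (6 h) and -2.44 (14 d), as did A2m at -1.42 and Apod at -1.35 (7 d). By limma's moderated F test over 7 differences 353 probes were called, 136 higher in SN and 217 higher in DR at their largest difference, and 323 within arrays, 173 higher in SN and 150 higher in DR, with 145 shared. The count was 226 and 235 without SN14d replicates 1 and 2, 230 without SN7d replicate 3 and 852 without DR14d replicate 1. Jun and Gap43 did not pass in the channel fit (adjusted p 0.0599 and 0.216); within arrays Gap43 did (8.94e-05).

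Both lesions called some of the same probes, whose controls were separate pools. Of the probes called over the courses 69 were higher in both, against 12.8 if the lists were independent (two-sided Fisher exact p = 6.12e-33). Another 19 were lower in both against 4.5 (Fisher exact p = 1.07e-07). Within arrays the numbers were 47 against 6.1 and 19 against 2.9. Across all 8455 probes, dim and unnamed ones included, the log2 changes of SN and DR at a time were little related. Pearson r ran from -0.135 to 0.125 at the 7 times and from -0.043 to 0.209 within arrays. Probes are not independent replicates, so no p is given for these correlations, and the Fisher tests treat probes as independent. Both courses also share each probe's estimate of the spread, so a probe with a small estimate tends to be called in both. The expected numbers and the Fisher tests leave this aside.

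Between the 7 SN and 7 DR pools paired by time, 2041 probes differed, 1069 higher in SN and 972 higher in DR. Higher in DR in all 7 pairs were the actin binder Pfn1 by a log2 difference of -2.38 ± 0.28, the membrane traffic GTPases Rab6a and Rab3a (-1.48 ± 0.10 and -1.31 ± 0.11) and Septin7 (-1.46 ± 0.16). The same held for the amino acid transporter Slc38a1 (-1.43 ± 0.10), the lipid enzyme Scd2 (-1.39 ± 0.10), the myelin protein Mbp (-1.36 ± 0.20) and Map1b (-1.29 ± 0.07). In the mean SN change minus the mean DR change within arrays, tested with the error of both controls, 4 of the 8 were called, Slc38a1 (-1.65 ± 0.30), Scd2 (-1.53 ± 0.21), Rab3a (-1.11 ± 0.22) and Map1b (-0.99 ± 0.22). Mbp (-1.86 ± 0.76), Rab6a (-0.95 ± 0.28), Septin7 (-0.77 ± 0.29) and Pfn1 (-0.61 ± 0.29) were not called there. The genes highest in SN were Taf9b (3.14 ± 0.10), Mlxipl (2.78 ± 0.12), Shb (2.73 ± 0.12), Camk2g (2.71 ± 0.11), Dnajb9 (2.59 ± 0.13) and Npy (2.42 ± 0.38). They were followed by Nphs1 (2.31 ± 0.15), Gpnmb (2.12 ± 0.10), Myog (2.12 ± 0.11), Limk2 (1.91 ± 0.11), Adam17 (1.75 ± 0.09) and Pex3 (1.67 ± 0.14). All 12 were also higher in the SN than in the DR control pool, 11 by at least 1.5-fold, and the within-array difference of changes called 2 of the 12, Npy (1.21 ± 0.28) and Pex3 (0.61 ± 0.13). Taf9b was at 0.46 ± 0.27, Mlxipl and Camk2g at -0.04, and Shb and Dnajb9 at 0.04. By that test 179 probes differed, 108 higher in SN and 71 higher in DR.

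The list test on these pools gave 29 oxidative phosphorylation genes higher in SN (16 higher, 2 lower, 11 not called, and 18 and 2 adjusted over the list alone; adjusted p = 6.21e-05). It gave 17 matrix genes higher in DR (7, and 7 adjusted over the list alone; adjusted p = 0.00302) and 17 synaptic genes higher in DR (6 in DR and 1 in SN, and 7 and 1 adjusted over the list alone; adjusted p = 0.015). None of the 3 calls held with an estimated correlation (adjusted p = 0.401 for each), and the other 23 lists were between 0.0774 and 0.646. For the change relative to the own control within arrays, the antigen presentation and growth-associated lists were higher in SN (adjusted p = 0.00297 and 0.00578; adjusted p = 0.0441 and adjusted p = 0.131 with an estimated correlation). The synaptic list was higher in DR (adjusted p = 0.00578, and adjusted p = 0.0483 with an estimated correlation).

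The 2 control pools differed at 2 probes, Nphs1, a kidney slit membrane protein, at 1.88 ± 0.36 higher in CON(SN) (adjusted p 0.0346) and an unnamed probe at 2.28. Without CON(SN) replicate 1, 2 or 3, or without CON(DR) replicate 1 or 3, limma called 0 of them, while 986 probes had an unadjusted p below 0.05 with all channels. Against the 2 control pools, limma called 1 probe in the SN pools, the neutrophil calcium-binding protein S100a8 at -1.32 ± 0.20 (adjusted p 0.0284), with 885 probes at an unadjusted p below 0.05. The count was 0 without 12, 24 or 72 h, 13 without 6 h, 5 without 7 d and 43 without 14 d. In the DR pools 202 were called, 72 higher, among them Snap25 at 1.82, Vsnl1 at 1.42, Ccl2 at 1.40 and Map1b at 1.11, and 130 lower. The lowest, Taf9b, Shb, Camk2g, Mlxipl and Dnajb9 at -2.50 to -1.90, were not called within arrays. The count fell to 77 without 48 h, 89 without 72 h, 120 without 12 h and 133 without arrays 22 and 24. From earlier (6 to 24 h) to later (48 h to 14 d) pools 5 probes rose, the acute phase inhibitor Serpina3n by 1.30, Cacna2d1 by 0.91, Aif1 by 0.75 (at a dimmer probe than in the macrophage list), the class II gene RT1-DMb by 0.65 and Spr by 0.58. Within arrays RT1-DMb was again called, at 0.69 (adjusted p 0.0348), and the other 4 were not (adjusted p 0.0633 to 0.0976). In the authors' deposited table none of the 5 passed (0.19 to 0.259). In this comparison limma called 0 probes without 6, 12 or 72 h (1051 at an unadjusted p below 0.05 with all times), 10 without 24 h, 8 without 7 d and 9 without 14 d.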

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

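Of the tests in this part, those on inferred arrays, the weighing of DR14d, the different change after both lesions and both tests of the synaptic list were chosen after the result was seen. For 38 named values, 30 from the paired SN and DR pools over 7 times and 8 from the channels of a pool, a value far from the others was looked for, and 2 had one, both in the paired pools; chance gives this in about 1 of 20 groups. Gpnmb, a glycoprotein of macrophages, was 2.71 higher in SN at 6 h against 1.86 to 2.16 at the other times. The myelin gene Mbp was at -2.75 at 24 h against -1.38 to -0.73.

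Changes that differed between the lesions by the interaction test are given as SN change minus DR change at the time of the largest difference. Of 43 named genes 29 passed, 26 of them also within arrays, and 353 probes passed in all. The values for genes higher in SN were 3.37 for Npy (14 d), 4.08 for Csrp3 (72 h), 2.75 for Atf3 (14 d), 3.46 for Gal (72 h), 1.69 for Reg3b (14 d; adjusted p 0.0972 within arrays), and 3.08 for Vip (14 d). They were 2.53 for Arg1 (72 h), 2.46 for Ucn (72 h), 2.65 for Ankrd1 (48 h), 2.95 for Rrad (48 h), 2.07 for RT1-Da (14 d), 2.29 for Tgm1 (48 h), 1.11 for Sprr1a (48 h) and 0.63 for Nfil3 (24 h; adjusted p 0.148 within arrays). Genes lower after SN at 7 d were Np4 (-2.39), Hbb (-1.54), Defa5 (-1.35), RatNP-3b (-2.19), Mcpt10 (-1.25) and Mcpt8 (-0.98), and Septin7 was at -1.81 at 72 h. Genes that rose more after DR were Snap25 (-1.88), Vgf (-0.92) and Ccl2 (-1.63) at 6 h, Apod (-1.35), Fn1 (-1.68; adjusted p 0.0681 within arrays) and A2m (-1.42) at 7 d, Sv2b (-2.44) at 14 d and Vsnl1 (-1.33) at 72 h.

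At DR14d 1029 probes were called in the channel fit and 100 within arrays. For differences between arrays, the slope of the partner channels' deviation on the DR14d change was 0.73 (r = 0.913) over the called probes, with -0.26 for the partner of replicate 1. Channels were joined into arrays by likeness, and the arrays of replicates 2 and 3 were picked because they stood apart, so this value decides nothing. For a change 14 d after the lesion, the slope of the within-array on the channel value was 0.32 (r = 0.761), on the same joins, which neither excludes it nor carries the full size. On the first principal component DR14d replicate 1 lay at 11.1 and replicates 2 and 3 at 39 and 41.7, though all are the same pool. DR48h replicate 4 and DR72h replicate 3, of other pools, lay at 39 and 37.8. That spread lies between hybridisations and not in the 14 d pool. The component covers all probes, so it does not tell how many of the 1029 calls follow it. Both explanations stay open for the called probes.

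Between the paired SN and DR pools 2041 probes were called. An offset between the SN and the DR arrays would also set the control pools apart: the slope of the control difference on the paired difference was 0.31 (r = 0.492). A different change after each lesion would remain within arrays relative to the own control, where the slope was 0.45 (r = 0.648). Both may contribute, and the design, with separate arrays for each series, keeps them from being told apart. Control differences were 1.55 and 1.83 for Taf9b and Mlxipl and 0.24 and 0.09 for Slc38a1 and Map1b.

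The synaptic vesicle list rose in the DR pools. The list was also called within arrays by camera (adjusted p = 0.00218). The arrays were inferred from the authors' deposited coefficients, so this does not decide on differences between arrays as the cause. Spinal cord tissue in the DR pools could bring synaptic transcripts. The 9 spinal cord and oligodendrocyte transcripts had a median change of -0.04 against 0.31 for the synaptic list. The standard error of the mean of those 9 was 0.11. Counted in it, their median lies too close to the bound of 0.15 set for excluding spinal cord tissue. Regulation in the neurons stays open and was not tested.

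Other assignments of the channels or pools to groups were counted, the real one included. The splits of channels exchange repeated hybridisations of single pools and leave aside that channels share arrays (correlation 0.774). They bear on the spread between hybridisations, not between animals or pools. As channels that share an array are not freely exchangeable, the shares of splits do not exclude chance. Splits with at least the real count were 2 of 100 for the SN course (417 against at most 435 in another). They were 3 of 100 for the DR course (660 against 764) and 1 of 100 for the interaction (353 against 167). Single times gave 1 of 35 for DR6h (346 against 107), 1 of 56 for DR12h (245 against 50) and 1 of 35 for DR48h (295 against 125). The gene lists gave 1 of 100 for SN (9 against 7) and 3 of 100 for DR (6 against 7). Where whole pools were exchanged, the real count was the largest for the paired pools (2041 against 379, 1 of 64) and for later against earlier pools (5 against 2, 1 of 100). Pools of a lesion share arrays, and the SN and the DR arrays were separate sets. Neither share therefore excludes chance, and an offset between these sets could also make the real pairing the largest. For the gene lists of the paired pools 26 of 64 exchanges gave as many calls (3 against 7), so chance cannot be excluded there. For the comparisons with 10 splits, these are too few for a share under 0.05. The real count and the highest other were 2 and 0 for the control pools, 20 and 0 for SN6h, 15 and 84 for SN12h, 42 and 1 for SN24h, 152 and 0 for SN48h, 157 and 199 for SN72h. They were 89 and 381 for SN7d, 153 and 0 for SN14d, 88 and 203 for DR24h, 151 and 69 for DR72h, 189 and 504 for DR7d, and 1029 and 388 for DR14d. As many calls as the real split came from 1 split (itself) for the control pools, SN6h, SN24h, SN48h, SN14d, DR72h and DR14d, from 2 for SN72h, SN7d and DR24h, from 3 for DR7d and from 5 for SN12h. Splits with several times the real count at SN12h, SN7d, DR24h and DR7d point to a structure of the samples, which was not tested. Leaving out 1 channel moved these counts by over 1.5 times. SN6h went to 3 and 5 (without CON(SN) replicate 2 or 3), 7 (SN6h replicate 1) and 9 (SN6h replicate 2 or 3), SN24h to 27 (CON(SN) replicate 2), SN48h to 97 (CON(SN) replicate 3) and 74 (SN48h replicate 1), and SN14d to 97 (CON(SN) replicate 3) and 82 (SN14d replicate 1). SN7d went to 52, 49 and 168 (CON(SN) replicates 1, 2 and 3), 51 and 48 (SN7d replicates 1 and 3), DR48h to 176 (DR48h replicate 4), DR72h to 82 (CON(DR) replicate 1) and 55 (DR72h replicate 3), and DR7d to 94 (CON(DR) replicate 1), 340 and 82 (DR7d replicates 1 and 2). The moves at SN12h, SN72h, DR6h, DR24h and DR14d are given with the single times, and DR12h did not move so far.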

How the results depend on the processing

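The within-array fits, the array as a random block, the removal of arrays 22 and 24, and the pool tests on within-array or deposited coefficients were chosen after seeing the data; the other alternatives were planned. Quantile scaling, median scaling, leaving out dim probes and no fold minimum each kept every count within 1.5 times of its value. With quantile scaling the list of myelinating Schwann cell markers lost its call for the SN mean (adjusted p = 0.0669). With the mean of a gene's probes that list (adjusted p = 0.0559) and the red blood cell, adipose and muscle list (adjusted p = 0.115) lost theirs. The planned random block needed all 26 arrays to be told by mutual best matches. The residuals gave 18 such pairs, and 17 of the 26 joined arrays were among them, so it was not run as planned.

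With no dye term the counts were 408 for the DR course, 226 for the interaction and 0 for the control pools. At an adjusted p of 0.01 they were 212 (SN course), 223 (DR course), 135 (interaction), 1282 (each time point, summed), 1088 (SN against DR pools paired by time), 18 (DR pools), and 0 for control pools, SN pools and later against earlier pools; in limma 986, 885 and 1051 probes of these last had an unadjusted p below 0.05. A 2-fold minimum gave 120 (SN course), 276 (DR course) and 968 (single times). Stricter limits lower counts by construction; for the rest the cause was not tested. The authors' deposited coefficients and errors gave 265 for the DR course and 1653 for single times, and in pool tests 3588 for the paired pools and 0 for later against earlier. With the array as a random block the interaction gave 1214 and the control pools 44. Within arrays the single times summed to 1865; without a dye term there, the counts were 135 (SN course), 110 (DR course), 73 (interaction) and 676 (single times). Without arrays 22 and 24 they were 402 (DR course), 3 (SN pools), 133 (DR pools) and 3 (later against earlier). The paired pools gave 3493 relative to the own control and 3603 within arrays, where later against earlier gave 3. As the 7 values of a lesion share its control, these counts and the 3588 do not count changes: with none simulated, 2952 to 3206 and 2798 to 3087 probes were called. With both controls in the error, the within-array count was 179. Lists called with an estimated correlation were 4 for SN and 0 for the paired pools, and 5 for the paired pools with the mean of a gene's probes.

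Leaving out 1 channel gave 300 to 605 probes for the SN course, 358 (without DR14d replicate 2) to 1201 (without DR14d replicate 1) for the DR course, 226 (without SN14d replicate 1) to 852 (without DR14d replicate 1) for the interaction, 0 to 2 for the control pools and 2214 to 3863 over single times. Leaving out 1 time gave 1404 to 2384 for the paired pools, 0 to 43 (without 14 d) for the SN pools, 77 (without 48 h) to 298 for the DR pools and 0 to 10 (without 24 h) for later against earlier.

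Called values that turned direction were Gap43 at SN12h (0.25 in the authors' deposited table and 0.03 within arrays), Camk2g at DR48h (0.35 within arrays), and the SN minus DR difference of Mlxipl and of Camk2g (-0.04 within arrays for each). Among values not called, the SN minus DR differences of Gap43 (-0.07) and Sox11 (-0.05) lay on the other side at 1.13 and 0.19 in the authors' deposited table and at 1.17 and 0.44 within arrays. The others were Stat3 SN72h (0.04 in that table and 0.08 within arrays, from -0.55), Vip DR6h (-0.01 in that table, from 0.60), Sprr1a DR6h (-0.19 there, from 0.19) and Gap43 DR72h (-0.39 without CON(DR) replicate 3, from 0.44). Within arrays 24 of the SN genes kept direction and side of the threshold, 1 lost its call and 1 turned. Of the DR genes 20 kept them, 6 lost the call, 2 gained it and 1 turned. With the authors' deposited coefficients 24 of the SN genes kept them, 1 lost its call and 1 turned, and of the DR genes 23 kept them and 6 lost the call. The replicate numbers did not pair the samples: deviations of channels with the same number correlated at r from -0.66 to 0.65, and 11 of 52 channels matched their own number best. With the replicate block the counts were 415 (SN course), 705 (DR course), 393 (interaction), 2 (control pools) and 2817 (each time point, summed), and DR12h went from 245 to 134.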

Other observations

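Defensins and genes of granulocytes, mast cells and red blood cells were looked at after the falls in the SN series were seen, so the tests in this part were chosen after the result. On the mean of 7 times, the defensins Np4 and Defa5 fell by 1.56 ± 0.18 and 1.38 ± 0.18 in SN and by 0.96 ± 0.18 and 0.95 ± 0.18 in DR. The basophil protease Mcpt8 fell by 1.14 ± 0.16 in SN (adjusted p 4.23e-06) and by 1.00 ± 0.16 in DR (adjusted p 3.62e-05), and was below the own control at 7 of 7 times in each, which share 1 control pool. S100a8 fell by 1.21 ± 0.27 and 0.96 ± 0.26, Mcpt10 by 1.18 ± 0.16 and 0.70 ± 0.15, Mcpt9 by 0.92 ± 0.19 and 0.86 ± 0.19, and the antimicrobial peptide gene Camp by 0.79 ± 0.18 and 0.74 ± 0.18. Hbb was below the own control at 6 of 7 times in each lesion.

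Other genes of these cells were not called on that mean in either lesion in the channel fit: Mcpt3, Mcpt4, Mcpt1, the mast cell chymase Cma1, the immunoglobulin E receptor genes Ms4a2 and Fcer1a, the red cell anion exchanger Slc4a1 and S100a9. Within arrays S100a9 was called in both (-0.59, adjusted p 0.022, and -0.58, adjusted p 0.0133). RatNP-3b fell by 1.28 ± 0.21 in SN and was at -0.52 ± 0.21 in DR (adjusted p 0.128), and Alas2, of red cell heme synthesis, was at -0.58 ± 0.17 in SN (adjusted p 0.0996) and fell by 0.63 ± 0.17 in DR. In the control pools Mcpt4 stood at 90.3 and 106 and Np4 at 495 and 412. The genes not called in the channel fit stood at 46 (Fcer1a) to 90.3 (Mcpt4) in CON(SN). In CON(DR) they stood at 48.7 (Fcer1a) to 125 (S100a9). Channel medians were 120 to 125, so a fall of these dim probes could have been missed.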
